A study of Acropora tenuis
Cladocopium goreaui and Acropora tenuis with 24 samples.

How the data were processed

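Coral larvae were raised in filtered seawater, part of them was exposed to the algae, and larvae were frozen at 3, 12, 48 and 72 h, per the labels. Total RNA was made into libraries with an Illumina TruSeq kit and sequenced on a HiSeq instrument, per the labels. The sample descriptions name a single flow cell for all libraries and no lanes, so no batch could be separated. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

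The submitters' processing notes name Bowtie2, RSEM and edgeR without versions. The symbiont table's title names express, with no version. Which step each tool served, the reference sequences and the strand setting are not given in the sources used here. The deposited coral counts are expected counts per feature, named as RSEM isoform counts in the table's title. A further coral table holds log2 values made by the authors. They were checked to be log2 of CPM (counts scaled to a common library total) plus 1, with a largest difference of 4.97e-14, so they carry no scaling between libraries beyond the library total. The deposited symbiont counts are expected counts per isoform of an assembled transcriptome. A further symbiont table deposited by the authors holds a normalized signal, which equals the count times a factor of the feature and a factor of the library. The 2 symbiont tables hold 6 further columns, 3 in each, that are named control and match no sample of the series; what they hold is not given in the sources used here, and they were not used.

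Expected counts were rounded to whole numbers. Features were kept by filterByExpr on the groups (minimum count 10), which left 19722 of 25393 coral features with 99.9% of counts and 1626 of 119820 symbiont features with 52.8% of counts. TMM factors ranged from 0.822 to 1.08 for coral and from 0.255 to 3.96 for symbiont libraries. Differences were tested with edgeR 4.0.16 (robust quasi-likelihood F test, group means, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over all features tested, and called at an adjusted p under 0.05 with no minimum fold change. The coral fit held all 24 libraries, so that the 8 groups shared the estimate of spread, and the symbiont fit the 12 infected libraries. Contrasts were infected against control at each time, the mean of the 4 effects, the difference of the effects at 12, 48 and 72 h from that at 3 h, and the times against 3 h in control larvae and in the alga. The time course of infected larvae and pairwise tests between times in control and infected larvae were added after seeing the data. The standard error of a log2 fold change was derived from the F value. CPM values use TMM-scaled library sizes, and log2 CPM values for principal components and shifts a prior count of 2.

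The symbiont share is the symbiont count total over the sum of coral and symbiont totals of a library. It was tested with an exact, two-sided permutation of the F statistic over all 369600 arrangements of the 12 libraries (Python 3.11.15, NumPy 2.4.6). Wilson intervals of the share (95%) cover counting error only. The columns named control could not be mapped to control larvae, so a background of algal counts in control larvae was not analysed here.

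Feature IDs are used as deposited. The files do not pair them with gene names and no annotation was used here, so the gene lists and cell type markers fixed in advance could not be built and none was tested. By a rule fixed before the data were examined, a comparison names the 2 features that rose and the 2 that fell with the smallest p among those called, with a mean of at least 1 CPM and no overlap between the libraries of the 2 groups. For a mean or test over several times overlap was not used, and tests with 3 degrees of freedom name the 2 features with the smallest p. Where nothing passed, the feature with the smallest p in each direction is given. Isoforms or copies with similar sequence share reads, and the counting can split them, so single symbiont isoforms are uncertain.

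The scripts were tested on simulated counts drawn at the spreads and library sizes of the real libraries, with known changes put in. Each feature had 1 mean, taken over all libraries. The simulated libraries held no other difference between groups, no library that stood apart and no correlated features. Recovery and false calls in the real libraries may therefore differ. For infected against control at 48 h (19472 features tested), edgeR recovered 11.9%, 61.2% and 92.4% of features changed 1.5-fold, 2-fold and 4-fold, with 6 false calls among 116. For the mean of 4 times it recovered 65.7%, 82.1% and 100%, for the difference between times 1.49%, 25.4% and 62.1%, and for the control time course 16.4%, 56.7% and 87.9%. In the same simulations DESeq2 made 17 false calls among 122 at 48 h and 22 among 99 for the difference between times.

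Alternatives were DESeq2 size factors, library totals without scaling, no filter on low counts, DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1), a minimum log2 fold change of 1, the replicate number as a block, each library left out in turn, the 6 libraries of a time alone, symbiont isoforms summed, and symbiont libraries thinned to the smallest. Summing coral isoforms was not run because the IDs do not show the gene. Other settings, given as chosen after seeing the data, left out the 3 libraries that stood apart, the 48 h groups or the features with most counts, or thinned the coral libraries. A library was said to stand apart where its mean chi-square per feature against both group mates was over 5 times that between the mates.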

Results

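Larvae of the reef coral Acropora tenuis were raised without algae and part of them was exposed to Cladocopium goreaui, a dinoflagellate alga that lives inside coral cells and is native to the adult colonies. Messenger RNA of both partners was sequenced together from larvae. The series holds 24 larval libraries in 8 groups of 3: infected larvae and unexposed control larvae, each sampled 3, 12, 48 and 72 h after exposure. Coral transcripts were counted over 25393 features in all 24 libraries, with 16288032 to 21868083 counts per library and 22437 to 23918 features detected. Algal (symbiont) transcripts were counted over 119820 features in the 12 infected libraries, with 84586 to 881635 counts per library. The comparisons ask which coral transcripts differed between infected and control larvae at each time, whether that difference changed with time, and what changed in the alga inside the larvae. The files do not pair feature IDs with gene names, so features are given by their IDs alone.

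The mean share of counts assigned to symbiont features was higher at 72 h than at 3 h, a difference that was tested only within all 4 times. It was 0.602% ± 0.137 of all counts at 3 h, 0.678% ± 0.152 at 12 h, 1.01% ± 0.271 at 48 h and 2.78% ± 1.77 at 72 h (mean ± SD, n = 3 infected libraries each). The mean at 72 h was 4.62 times that at 3 h. Among single libraries the share ran from 0.452% in infected 3 h replicate 3 (95% Wilson interval 0.449 to 0.455%) to 4.37% in infected 72 h replicate 2 (4.37 to 4.38%), and infected 72 h replicate 3 had 0.877%. An exact permutation test of the F statistic over the 4 times, two-sided, gave p = 0.0382 (12 libraries). The p lay above 0.05 when any of 8 single libraries was left out, 0.0564 without infected 72 h replicate 2 and 0.0549 to 0.0577 for the other 7, while the ratio of 72 h to 3 h stayed between 3.30 and 6.20.

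**Figure D1:**
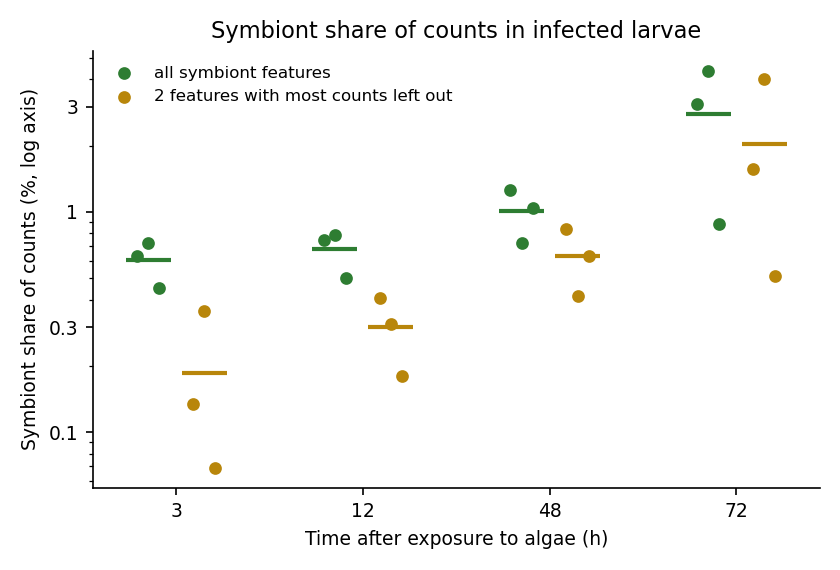
Share of all counts in a library that was assigned to symbiont features (percent, log axis) against time after exposure (h), for the 12 infected libraries. Points are libraries and bars are means of 3. With all symbiont features the means rise from 0.602% at 3 h to 2.78% at 72 h, and with the 2 features with most counts left out from 0.186% to 2.03%.

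A pair of symbiont features, TR8551|c0_g1_i1 and TR94643|c0_g1_i1, took 8.71 to 84.8% of the symbiont counts of a library. These 2 were picked because they had the most counts. Their summed counts ranged from 62879 to 301163, a 4.79-fold range (1.70-fold without infected 72 h replicate 1, the next highest sum being 106818), while the counts of all other symbiont features ranged from 12837 to 804884, a 62.7-fold range. With the 2 features left out, the symbiont share was 0.186% ± 0.150 at 3 h, 0.299% ± 0.115 at 12 h, 0.629% ± 0.212 at 48 h and 2.03% ± 1.79 at 72 h (n = 3 each). The mean at 72 h was then 10.9 times that at 3 h (exact permutation p = 0.0368). Without single libraries this ratio ran from 5.58 (infected 72 h replicate 2) to 20.0 (infected 3 h replicate 2), and the exact permutation p lay above 0.05, at 0.0553 to 0.0770, without any of 8 libraries.

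Coral libraries spread along 1 main axis that ordered the groups by time only in part. The 3 h infected libraries, control 3 h replicate 1 and 4 of the 6 libraries of 12 h lay at one end of the main axis of variation, which held 38.1% of the variance, and the 72 h infected libraries and infected 48 h replicate 1 lay at the other. The 72 h control libraries lay between, as did control 3 h replicates 2 and 3, control 12 h replicate 2 and infected 48 h replicate 3, and the 48 h control libraries lay apart on the second axis, which held 11.8%. Infected 12 h replicate 1, control 3 h replicate 1 and control 12 h replicate 2 stood apart from the other 2 libraries of their groups. Their mean rank correlations with their own group were 0.963, 0.981 and 0.967. A group whose 3 libraries all differ is not marked by this rule, which sets a library against the agreement of its 2 mates. In infected 48 h larvae the 3 pairs had mean chi-square values per feature of 47.6, 80.2 and 69.7. Each of these infected 48 h libraries had its highest rank correlation with a library of another group. No library pair of a group agreed within sampling noise: the lowest mean chi-square per feature was 3.82 for coral and 2.65 for symbiont counts.

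**Figure D2:**
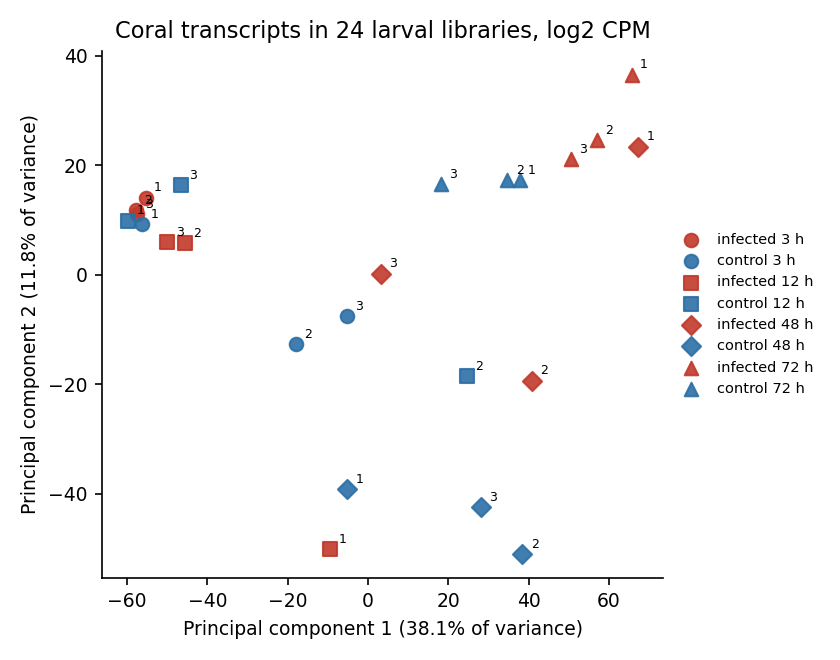
Principal components 1 and 2 of log2 CPM of coral features in the 24 libraries (arbitrary units); color gives infected or control, the marker gives the time, and the small digit gives the replicate. Infected 3 h libraries lie at the left, infected 72 h libraries at the upper right, and the 3 control 48 h libraries at the bottom, as does infected 12 h replicate 1.

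At 3 h, 1 coral feature differed between infected and control larvae. aten_0.1.m1.22841.m1 was lower in infected larvae, at 14.6 ± 0.620 CPM (counts scaled to a common library size) against 27.9 ± 2.85 (SD, n = 3 each), a log2 fold change of -0.93 with a standard error (SE) of 0.15 (edgeR adjusted p = 0.0431). aten_0.1.m1.29230.m1 had the smallest p among features with a higher mean in infected larvae, with a log2 fold change of 1.09 (SE 0.20), and did not pass (edgeR adjusted p = 0.111). Without adjustment 1548 of 19722 features had p under 0.05, against 986.1 expected by chance. The call was lost, with 0 features called, without any of the 3 infected libraries or without control replicate 2 or 3. Without control 3 h replicate 1, which stood apart, 415 were called, without it and the other 2 libraries that stood apart 2075, and DESeq2 called 42.

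**Figure D3:**
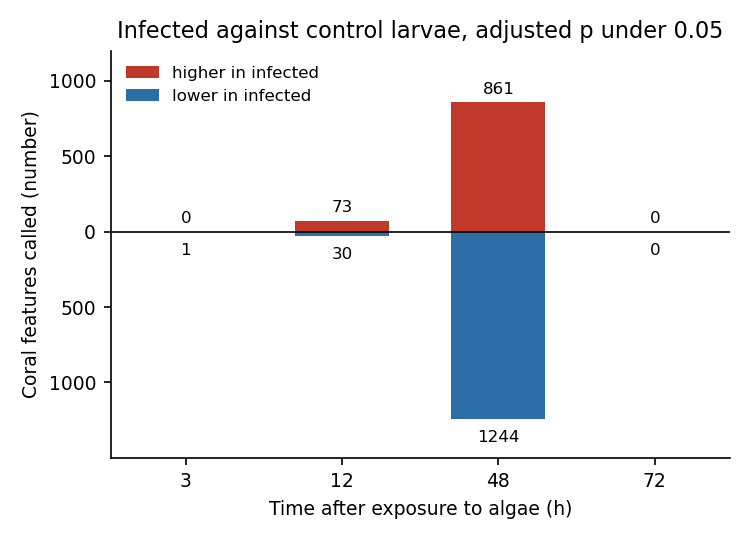
Number of coral features called at an adjusted p under 0.05 (edgeR) against time after exposure (h), with features higher in infected larvae above the zero line and lower ones below. Counts are 0 and 1 at 3 h, 73 and 30 at 12 h, 861 and 1244 at 48 h, and 0 and 0 at 72 h.

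At 12 h a small set of coral features rose sharply in infected larvae. aten_0.1.m1.17331.m1 stood at 889 ± 178 CPM in infected and 15.5 ± 6.39 in control larvae (SD, n = 3 each; log2 fold change 5.84, SE 0.38; edgeR adjusted p = 3.36e-08), and aten_0.1.m1.17333.m1 at 162 ± 55.4 against 4.64 ± 0.779 CPM (log2 fold change 5.13, SE 0.28; edgeR adjusted p = 4.91e-10). In infected larvae aten_0.1.m1.17331.m1 was at 22.7 ± 1.41 CPM at 3 h and 7.55 ± 2.37 at 48 h. The features that fell most clearly were aten_0.1.m1.14429.m1, at 108 ± 4.60 against 203 ± 24.4 CPM, and aten_0.1.m1.786.m1, at 77.2 ± 6.50 against 139 ± 25.4 CPM. In all, 103 features were called, 73 higher and 30 lower in infected larvae, of which 40 and 9 changed by a log2 value of at least 1 and 11 higher ones by at least 4-fold.

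Of the 73 features higher at 12 h, the median log2 fold change was 1.06 at 12 h, and -0.05, 0.01 and 0.02 at 3, 48 and 72 h. For the 30 lower ones it was -0.84 at 12 h, and 0.26, -0.24 and -0.36 at 3, 48 and 72 h, with the opposite sign at 48 h for 7. The test of a difference between times also called 49 of the 73 higher and 22 of the 30 lower features. The count depended on single libraries: 669 without control 12 h replicate 2, 30 without control replicate 1, 35 without control replicate 3 and 203 without infected replicate 3. Without infected replicates 1 and 2 it was 92 and 122. Of the 103 features first called, 57, 68 and 76 were called again without infected replicates 1, 2 and 3. Without control replicates 1, 2 and 3, 30, 102 and 34 of them were. DESeq2 called 534, the 6 libraries of 12 h fitted alone gave 2, and 916 were called with the 3 libraries that stood apart left out.

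At 48 h the fit over all 24 libraries called the most features, and most of them had moved in the control larvae. aten_0.1.m1.35044.m1 was at 134 ± 4.00 CPM in infected and 275 ± 5.94 in control larvae (log2 fold change -1.04, SE 0.08), and aten_0.1.m1.15042.m1 at 25.1 ± 1.56 against 64.7 ± 8.78 CPM (log2 fold change -1.36, SE 0.11; edgeR adjusted p = 1.42e-07 for both). At 3, 12 and 72 h the control means of aten_0.1.m1.35044.m1 were 129, 134 and 151 CPM, and those of infected larvae 140, 119 and 146 CPM. aten_0.1.m1.10214.m1 was higher in infected larvae, at 17.3 ± 3.62 against 3.99 ± 0.837 CPM, and so was aten_0.1.m1.15373.m1, at 63.0 ± 1.98 against 24.3 ± 0.993 CPM (SD, n = 3 each). The control 48 h libraries had the fewest coral features detected, 22437 to 23085 against 23204 to 23918 in the other 21. In all, 2105 features were called, 861 higher and 1244 lower in infected larvae, with median log2 fold changes of 0.68 and -0.69, and 230 and 291 of them changed by a log2 value of at least 1.

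For each feature called at 48 h, the 48 h mean of each group was set against the mean of that group's 12 h and 72 h values. The control larvae had moved further than the infected larvae for 751 of the 861 higher features (87.2%) and for 1131 of the 1244 lower ones (90.9%). The share over all features tested was not computed. The 12 h means held infected replicate 1 and control replicate 2, which stood apart, and the shifts were not computed without them. The median shift of the higher features was -0.48 log2 units in controls and 0.11 in infected larvae, and that of the lower features 0.58 and -0.01. At 12 h, set against 3 h and 48 h in the same way, the controls had moved further for 0 of the 73 higher features and 7 of the 30 lower ones. The 48 h count was 1062 without infected 48 h replicate 1, 1359 without control replicate 1 and 1337 without control replicate 2. It was 660 with the 6 libraries of 48 h fitted alone, where those of 72 h gave 1107, and 3744 with the 3 libraries that stood apart left out.

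**Figure D4:**
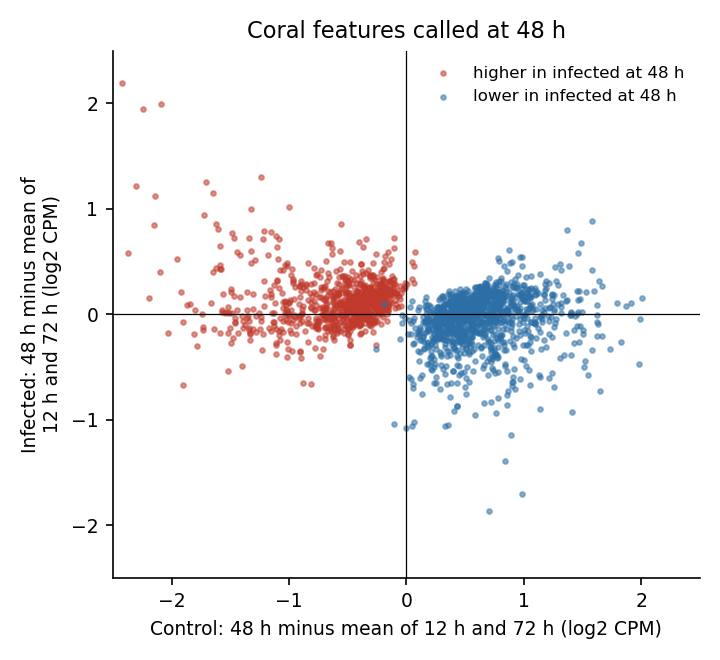
For each coral feature called at 48 h, the shift of control larvae (x axis) and infected larvae (y axis) at 48 h from the mean of 12 h and 72 h, in log2 CPM; 10 called features lie outside the axes. Points spread mainly along the x axis, with median control shifts of -0.48 for the 861 features higher in infected larvae and 0.58 for the 1244 lower ones.

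At 72 h no coral feature passed in the fit over all 24 libraries, although the groups were often apart. aten_0.1.m1.14045.m1 was at 733 ± 46.3 CPM in infected and 1764 ± 151 in control larvae (log2 fold change -1.27, SE 0.23), and aten_0.1.m1.792.m1 at 9.39 ± 1.86 against 3.90 ± 0.641 CPM (log2 fold change 1.27, SE 0.23; SD, n = 3 each; edgeR adjusted p = 0.171 for both). The count of calls was 0 with edgeR and with limma-voom and 17 with DESeq2, and 1834 features had an unadjusted p under 0.05 against 986.1 expected. The 3 infected libraries did not overlap the 3 controls for 28.7% of features, against 10% by chance. With the 6 libraries of 72 h fitted alone, where the spread is estimated from that time only, edgeR called 1107 features, 434 higher and 673 lower in infected larvae. aten_0.1.m1.14045.m1 then had an edgeR adjusted p of 0.000195, within a range of 0.000195 to 1 over all alternatives. With the 3 libraries that stood apart left out, 173 were called.

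**Figure D5:**
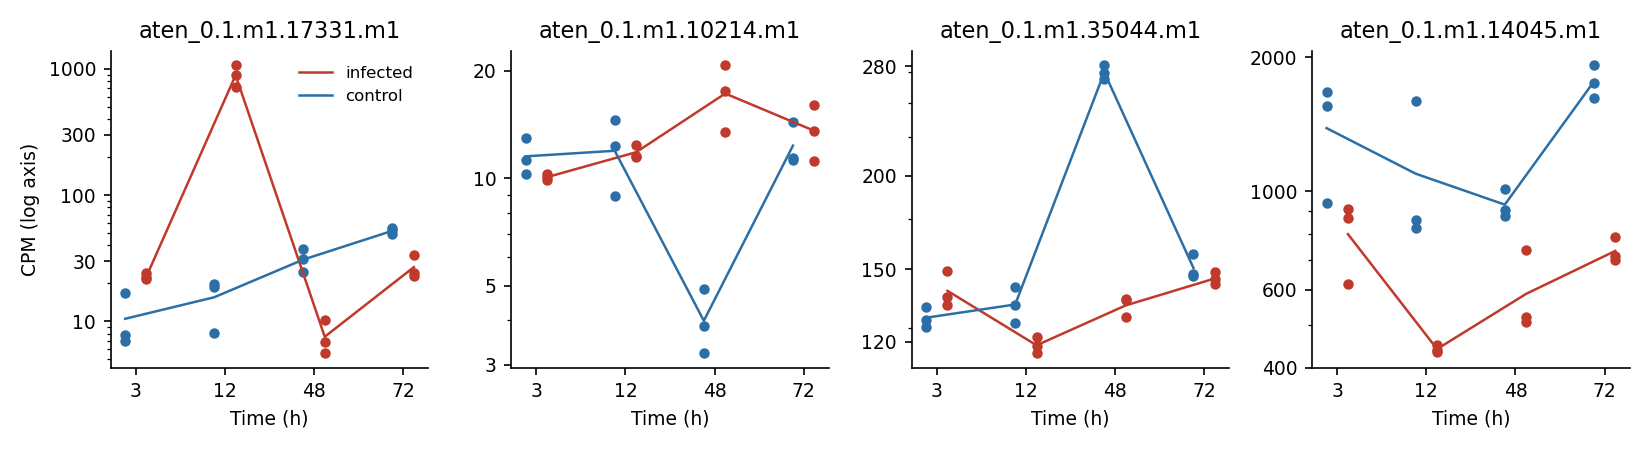
CPM (log axis) of 4 coral features against time (h) in infected and control larvae; points are libraries and lines join means of 3. aten_0.1.m1.17331.m1 peaks at 889 CPM in infected larvae at 12 h, aten_0.1.m1.10214.m1 and aten_0.1.m1.35044.m1 have their extreme control means at 48 h (3.99 and 275 CPM), and aten_0.1.m1.14045.m1 is at 733 CPM in infected and 1764 in control larvae at 72 h.

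Averaged over the 4 times, 700 coral features differed between infected and control larvae, 267 higher and 433 lower in infected larvae. aten_0.1.m1.15373.m1 (log2 fold change 0.55, SE 0.07; edgeR adjusted p = 0.000118) and aten_0.1.m1.17333.m1 (1.03, SE 0.13; edgeR adjusted p = 0.000142) were higher. The mean of aten_0.1.m1.17333.m1 rested on 12 h, with effects of 0.19, 5.13, -0.35 and -0.86 at 3, 12, 48 and 72 h. aten_0.1.m1.14429.m1 (-0.59, SE 0.07) and aten_0.1.m1.1106.m1 (-0.60, SE 0.07; edgeR adjusted p = 7.23e-05 for both) were lower. The mean of aten_0.1.m1.1106.m1 rested mainly on 48 h, with effects of -0.19, -0.15, -1.70 and -0.37 at the 4 times. The effect had the same sign at all 4 times for 163 of the 267 higher and 213 of the 433 lower features, and it was largest at 48 h for 197 and 337 of them. Of the 700, 28 reached a mean log2 change of at least 1. Without the 48 h libraries 6 features were called. The count was 1756 with the 3 libraries that stood apart left out, 1180 with DESeq2, and 360 to 1086 without single libraries.

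The infection effect itself differed between times for 503 coral features. aten_0.1.m1.17333.m1 and aten_0.1.m1.17331.m1 had the smallest p (edgeR adjusted p = 1.4e-08 and 1.11e-07, F test with 3 degrees of freedom), and for both the effect at 12 h exceeded that at 3 h, by 4.94 and 4.72 log2 units. The largest departure of the effect (infected minus control) from that at 3 h was a lower effect at 48 h for 279 features, a higher one at 48 h for 87, a higher one at 12 h for 80 and a lower one at 12 h for 44. Without the 48 h libraries 30 features were called. The count was 3717 with the 3 libraries that stood apart left out, 1707 with DESeq2, and 230 to 1426 without single libraries.

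Control larvae, which hold no added algae, also changed over the 4 times, with 2774 coral features called. aten_0.1.m1.27516.m1 was at 29.2 ± 3.05 CPM at 3 h, 28.3 ± 1.06 at 12 h, 82.4 ± 5.97 at 48 h and 31.9 ± 1.74 at 72 h (edgeR adjusted p = 1.24e-09). aten_0.1.m1.15042.m1 followed the same course, at 24.3 ± 0.518, 25.7 ± 1.69, 64.7 ± 8.78 and 24.2 ± 0.506 CPM (SD, n = 3 each; edgeR adjusted p = 8.28e-09). The largest departure from 3 h was a rise at 48 h for 1356 features and a fall at 48 h for 788. The balance of rises and falls depended on the scaling. For 48 h against 3 h, edgeR with TMM called 1391 higher and 824 lower, and DESeq2 1613 and 1128. With library totals it was 849 and 1010, and with limma-trend on the deposited values 917 and 1032. Against 3 h, pairwise tests called 0 features at 12 h (590 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0), 2215 at 48 h and 4 at 72 h (DESeq2 228, limma-trend 75). The 12 h count was 207 without control 12 h replicate 2 and 1784 with the 3 libraries that stood apart left out. The 48 h count was 1216 without control 3 h replicate 1 and 1210 without control 48 h replicate 2. The 72 h count was 0 to 1 without single libraries and 40 with the 3 libraries that stood apart left out. The count of 2774 was 244 without the 48 h libraries, 4729 without control 12 h replicate 2, 1839 without control 12 h replicate 1, 1432 without control 48 h replicate 2 and 6877 with the 3 libraries that stood apart left out.

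In the alga, no feature passed in any of the 4 tests against the earliest time with edgeR, TMM and the filter on low counts. TR63227|c0_g1_i2 came nearest: it had 0 counts in each of the 3 infected 3 h libraries, 27, 14 and 3 counts in the 12 h libraries, 12, 22 and 14 at 48 h, and 56, 174 and 23 at 72 h (edgeR adjusted p = 0.0702, 0.224 and 0.0522 against 3 h). Among features with lower values than at 3 h, the smallest p belonged to TR64215|c0_g2_i4 at 12 h, with 4, 0 and 0 counts against 4, 16 and 1 at 3 h (edgeR adjusted p = 0.269). At 48 h it belonged to TR60490|c0_g1_i1, with 46.5 ± 17.4 against 204 ± 43.0 CPM (edgeR adjusted p = 0.224), and at 72 h to TR64017|c0_g1_i1, with 81.8 ± 35.8 against 297 ± 121 CPM (edgeR adjusted p = 0.194). For the latter, limma-trend on the deposited values gave a log2 fold change of 1.45, the opposite direction (limma adjusted p = 0.0326). The median of all tested features in that fit was 1.84, so this feature still lay below the typical one. The filter left 1626 features to test.

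Of these 1626 symbiont features, 89, 110 and 109 had an unadjusted p under 0.05 at 12, 48 and 72 h against 3 h, and 82 in the test over all times, where 81.3 are expected by chance. DESeq2 called 0, 1, 10 and 25 features in the same tests, limma-voom 0, 0, 4 and 4, limma-trend on the deposited values 0, 0, 1582 and 955, and edgeR without a filter on low counts 2, 10, 45 and 222. All 1582 were higher at 72 h than at 3 h, and the median log2 fold change of all tested features in that fit was 1.84. With library totals in place of TMM the counts were 5, 29, 749 and 39, and the median log2 fold change of all tested features was then 0.78, 1.66 and 2.13 at 12, 48 and 72 h, against 0.07, 0.13 and 0.13 with TMM. Of the 749, 746 were higher at 72 h. In these 2 settings most features thus shifted together at 72 h, and the calls do not mark single features. In simulated libraries of this depth, the 72 h against 3 h test recovered 11.9% of features changed 2-fold, 65.7% of those changed 4-fold and 80.3% of those changed 8-fold. Most 2-fold changes were thus not detectable in simulated libraries of this depth, which held no other difference between groups.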

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

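The features below were named by a rule fixed in advance, and the tests of explanations for the 48 h controls and the alternatives without the 48 h groups, without the 3 libraries that stood apart, without the features with most counts and with thinned coral libraries were chosen only after results were seen. The infection effect on coral transcripts differed between the 4 times for 503 features (edgeR, test of the difference with 3 degrees of freedom). Among the features named in the report, aten_0.1.m1.17333.m1 (edgeR adjusted p = 1.4e-08) and aten_0.1.m1.17331.m1 (1.11e-07) had effects of 5.13 and 5.84 log2 units at 12 h and -0.35 and -2.03 at 48 h. The effect also differed for aten_0.1.m1.14429.m1 (edgeR adjusted p = 0.00462) and aten_0.1.m1.786.m1 (0.00148), named at 12 h, and for aten_0.1.m1.22841.m1 (0.0174) and aten_0.1.m1.29230.m1 (0.0224), named at 3 h. It differed for aten_0.1.m1.35044.m1 (edgeR adjusted p = 2.49e-05), aten_0.1.m1.15042.m1 (2.6e-05), aten_0.1.m1.10214.m1 (0.000129) and aten_0.1.m1.15373.m1 (0.0025), named at 48 h, for aten_0.1.m1.1106.m1 (0.000129), named for the mean of the times, and for aten_0.1.m1.27516.m1 (3.79e-05), named for the control time course. The features named at 72 h did not pass this test, aten_0.1.m1.792.m1 with an edgeR adjusted p of 0.128 and aten_0.1.m1.14045.m1 with 0.386.

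Most of these differences lay at 48 h, where control larvae stood apart from the controls of the other times. Leaving out the 10 coral features with most counts hardly changed the calls at 48 h, 2099 against 2105. Both fits used TMM scaling and other features were not left out, so this test does not exclude features taking many counts as a cause. Library depth is excluded as the cause of these calls, since 2030 were called with all coral libraries thinned to the smallest total. For labels of single libraries swapped between infected and control larvae at 48 h, 0 of the 3 control 48 h libraries lay closer to the infected 48 h libraries than to their own group. This does not exclude such a swap, because closeness did not always follow the labels. Infected 48 h replicate 3 lay closer to the controls (mean rank correlation 0.979) than to its own group (0.978). An exchange of the labels of both whole 48 h groups, a single wrong label of that library, a difference in culture, handling or library complexity (the 3 had the fewest features detected, 22437 to 23085) and a biological difference of larvae without algae were not tested and remain open: the algal counts go with the labels (share without the 2 features with most counts 0.629% at 48 h, between 0.299% at 12 h and 2.03% at 72 h, and 195804 symbiont counts in that library), but no algal count of control larvae was at hand to set against them, and the labels give no batch.

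Regroupings of the libraries show what chance alone can give. For the difference between times, 4 of 100 regroupings, the real one included, gave as many calls. These regroupings shuffled infected and control labels within each time, which removes any infection effect and not only its difference between times. The share of 4 in 100 therefore cannot decide on chance for this difference, and a random draw of 100 does not fix it firmly. The highest other gave 984 against 503, which points to a structure of the samples. For the mean of the 4 times the real grouping alone reached its 700 calls among 100, the highest other giving 249. With 3 libraries against 3 there are 10 regroupings, and the share cannot go under 0.05. There the real grouping and the highest other gave 1 and 0 calls at 3 h (1 as large), 103 and 681 at 12 h (3 as large), 2105 and 0 at 48 h (1 as large) and 0 and 0 at 72 h (10 as large). A real count of 0 is reached by every regrouping, so the value at 72 h says nothing on chance. The 681 calls at 12 h came from infected replicates 1 and 3 with control replicate 2 set against the rest, which points to a structure of the samples. With the 6 libraries of a time fitted alone, the pairs were 1 and 3 at 3 h (3 as large), 2 and 0 at 12 h, 660 and 2 at 48 h and 1107 and 0 at 72 h (1 as large in each of these 3).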

How the results depend on the processing

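Settings that left out the 3 libraries that stood apart, the 48 h groups or the features with most counts, or thinned the coral libraries, and the pairwise tests between times of larvae, were chosen only after results were seen. For the 27 results on named features, 522 of 569 alternatives kept direction and side of the threshold, 18 were weaker, 26 stronger and 3 reversed. Symbiont depth limits its tests, with 1626 of 119820 features tested. Coral isoform sums were not run because the IDs do not show the gene, and gene list tests with an estimated correlation were not run because no names are paired with the IDs. Where no reason is given below, the cause was not tested.

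Coral calls changed as follows. At 3 h (1 call) a minimum log2 change of 1, library totals, limma-voom, limma-trend on the deposited values and thinning gave 0, DESeq2 42, and leaving out the 3 libraries 2075. At 12 h (103) the minimum log2 change gave 49, library totals 68, DESeq2 534, the 6 libraries alone 2 and leaving out the 3 libraries 916. At 48 h (2105) the minimum gave 521, the 6 libraries alone 660 and leaving out the 3 libraries 3744. At 72 h (0) DESeq2 gave 17, the 6 libraries alone 1107 and leaving out the 3 libraries 173. For the mean (700) the minimum gave 28, DESeq2 1180, leaving out the 3 libraries 1756 and leaving out 48 h 6. For the difference between times (503) the minimum gave 256, library totals 295, DESeq2 1707, limma-trend 319, leaving out the 3 libraries 3717 and leaving out 48 h 30. For the control time course (2774) the minimum gave 606, leaving out the 3 libraries 6877 and leaving out 48 h 244. A minimum fold change lowers a count by construction.

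Symbiont calls (0 in each test) at 12, 48 and 72 h against 3 h and over all times were 5, 29, 749 and 39 with library totals, 2, 10, 45 and 222 without a filter, 0, 1, 10 and 25 with DESeq2, 0, 0, 4 and 4 with limma-voom, 0, 0, 1582 and 955 with limma-trend on the deposited values, 0, 2, 2 and 3 with isoforms summed, and 0, 0, 1 and 0 without the 2 features with most counts. TR60490|c0_g1_i1 reversed at 48 h to a log2 value of 0.24 with limma-trend, and TR64017|c0_g1_i1 at 72 h to 0.46 with library totals and 1.45 with limma-trend, where it passed (limma adjusted p = 0.0326). These values lay below the medians of all tested features in the same fits, 0.67, 2.13 and 1.84. At 72 h, 746 of the 749 calls with library totals and all 1582 with limma-trend were higher than at 3 h.

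Single libraries left out moved the calls within these ranges. At 3 h it was 0 to 415 (415 without control replicate 1, 0 without any other of the 6). At 12 h it was 30 to 669 (infected replicate 3 203, control replicates 1, 2 and 3 30, 669 and 35). At 48 h it was 1062 to 2536 (infected replicate 1 1062, control replicates 1 and 2 1359 and 1337), and at 72 h 0 to 0. The mean had 360 to 1086 (infected 3 h replicate 2 406, infected 48 h replicates 1 and 3 437 and 1086, infected 72 h replicate 1 360, control 3 h replicate 2 427, control 12 h replicate 1 454, control 72 h replicates 2 and 3 408 and 404). The difference between times had 230 to 1426 (infected 3 h replicate 3 315, infected 12 h replicate 1 822, infected 48 h replicates 1, 2 and 3 327, 261 and 804, control 3 h replicates 1, 2 and 3 1426, 290 and 300, control 12 h replicate 2 1389, control 48 h replicates 1 and 2 292 and 230, control 72 h replicate 3 334). The control time course had 1432 to 4729 (control 12 h replicates 1 and 2 1839 and 4729, control 48 h replicate 2 1432). Symbiont tests had 0 to 3 at 12 h (3 h replicate 2 1, 12 h replicate 3 3), 0 to 1 at 48 h (3 h replicate 2 and 48 h replicate 3 1), 0 to 3 at 72 h (3 h replicate 2 1, 72 h replicate 2 3) and 0 to 2 over all times (3 h replicate 2 and 48 h replicate 2 2, and 1 without 3 h replicate 1, 12 h replicate 3, 48 h replicate 1 or 3, or 72 h replicate 2 or 3). The ratio of symbiont shares had 3.30 to 6.20, with an exact permutation p of 0.00188 to 0.0577.

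The replicate numbers did not clearly pair the samples: deviations of same-numbered coral libraries correlated at -0.28 to 0.17 at 12 h and at 0.01 to 0.08 at 72 h. The highest value of differently numbered libraries was 0.34 at 12 h, above the same-numbered ones, but 0.03 at 72 h, below the highest of them. With 3 libraries per group this check cannot exclude a pairing. With the replicate number as a block, 0 features were called at 3 h, 2 in the alga at 72 h and 1 over all times, the share ratio stayed 4.62 with an exact permutation p of 0.0712, control larvae at 72 h against 3 h gave 1 call (4 without the block) and infected larvae at 72 h against 48 h 1 (12 without), and no other count of calls moved over 1.5 times.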

Other observations

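The time course of infected larvae, the pairwise tests between times in control and infected larvae, and the tests on the libraries that stood apart and on the 2 symbiont features were chosen only after results were seen. In infected larvae 5479 coral features were called over time (edgeR, 3 degrees of freedom), and 7685 with the 3 libraries that stood apart left out, against 2774 and 6877 in control larvae, and the difference of these counts was not tested. The largest departure from 3 h was a fall at 72 h for 2034 features and a rise at 72 h for 1478, while 854 rose most at 48 h and 501 at 12 h. Against 3 h, 208 features were called at 12 h, 3551 at 48 h and 5019 at 72 h, of which 2402 rose and 2617 fell. Between 48 h and 72 h 12 were called. Without single libraries the 12 h count ran from 37 to 610, the 48 h count from 2 (without infected 48 h replicate 1) to 4861, the 72 h count from 3110 to 4146, and the count between 48 h and 72 h from 0 to 403. With DESeq2 and with the 3 libraries that stood apart left out, the 12 h count was 884 and 739, and the 48 h count 4214 and 5961. In the same 2 settings the count between 48 h and 72 h was 96 and 300.

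The 3 libraries that stood apart were weighed against a library taken from another group of the series and another pace of the change over time. For infected 12 h replicate 1 the highest mean rank correlation with another group, 0.968 (control 3 h), and the correlation across features of its deviation with the infected change from 3 h to 72 h, 0.280, leave both open. The first lay below 0.978, the lowest of a library not standing apart with its own group, but above the 0.967 of control 12 h replicate 2. For control 3 h replicate 1 both remain possible, at 0.992 (infected 3 h) and -0.506. For control 12 h replicate 2 both remain possible too, at 0.986 (control 72 h) and 0.635. Libraries that did not stand apart reached -0.587 (control 12 h replicate 1), 0.568 (infected 48 h replicate 1) and -0.549 (infected 48 h replicate 3) with the same change. The -0.506 is therefore not particular to control 3 h replicate 1. Features are not independent, so these correlations carry no p, and no biological explanation was tested.

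The 2 symbiont features with most counts may hold reads that do not come from the alga, since their counts did not detectably follow those of all other symbiont features. The slope between the log2 counts was 0.12 (95% bootstrap interval -0.10 to 0.57, 12 libraries), with a Pearson r of 0.31 (permutation p = 0.295). A slope of 1, in proportion, lies outside the interval, but the source of the reads remains open. The slope was 0.35 without the 2 farthest libraries, infected 72 h replicate 2 and infected 3 h replicate 3, and -0.02 without infected 72 h replicate 1. No biological explanation was tested.

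Regroupings of the remaining tests gave these values. For the control time course 2 of 100, the real one included, gave as many calls, a share under 0.05 that a random draw of 100 does not fix firmly, and the highest other gave 4282 against 2774, which points to a structure of the samples. For the infected time course 1 of 100 did, the highest other giving 3561 against 5479. For the alga over all times 100 of 100 gave at least the real 0, the highest other giving 3. Every regrouping reaches a real count of 0, so such a share cannot decide on chance. This holds for each test with a real count of 0 below. With 10 regroupings the share cannot go under 0.05. There the real grouping and the highest other gave, in control larvae, 0 and 2165 for 12 h against 3 h (10 as large), 2215 and 0 for 48 h against 3 h, 4 and 0 for 72 h against 3 h and 1977 and 0 for 72 h against 48 h (1 as large in each of these 3). The 1977 was 1043 to 1466 without single libraries and 3901 with the 3 libraries that stood apart left out. The 2165 calls point to a structure of the samples. In infected larvae they gave 208 and 0, 3551 and 0 and 5019 and 0 for 12, 48 and 72 h against 3 h (1 as large each), and 12 and 40 for 72 h against 48 h (2 as large). In the alga they gave 0 and 2, 0 and 1 and 0 and 0 for 12, 48 and 72 h against 3 h (10 as large each).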
